A study of Mus musculus with 4 samples.

How the data were processed

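The samples were total RNA of whole C57BL/6 embryos at E18.5, 2 wild-type and 2 with a knockout of ER-alpha, isolated with TRIzol, per the labels' protocols. MicroRNAs were read with TaqMan assays on an Applied Biosystems 7900HT instrument over 40 cycles, per the labels' protocols. The deposited values are threshold cycles (Ct), per the file headers, with 1 value per well and 4 wells for U6. The threshold, baseline, any normalization by the authors and the assay version were not given in the sources used here, and no genome build is needed for these values. Wells without amplification are written as undetermined in 3 of the files. In the file of wild-type replicate 1 every assay has a number, 39 assays stand at 40.3, above the last cycle of the protocol, and all 380 wells other than U6 share a constant of 0.273, as the values themselves show. Those 39 were treated as not amplified, and the constant was kept in the main analysis. Lines without an assay, 1141 in the file of ER-alpha knockout replicate 2, were not used.

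The deposited Ct values were taken as raw, although any earlier normalization is unknown and wild-type replicate 1 holds the constant described above. Each sample was centred on the median Ct of the microRNAs detected in all 4 samples (Ct of 35 or lower). The relative level on a log2 scale is minus this centred Ct. This takes 1 cycle as a doubling, and an assay of lower efficiency would have smaller true fold changes. Centring removes any change of all microRNAs together, so that shift was read against the mean Ct of the 5 small-RNA controls (MammU6, U87, Y1, snoRNA135 and snoRNA202). The median Ct of the tested microRNAs was 29.2 and 27.4 in wild-type replicates 1 and 2, and 28.2 and 27.8 in ER-alpha knockout replicates 1 and 2. Only 2 samples per group limit the precision. A plant control assay read in wild-type replicate 1 only was left out of the comparisons.

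Levels were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, group as the only term), with Benjamini-Hochberg adjustment over the 229 tested microRNAs. The estimated prior degrees of freedom were infinite, so all assays share 1 variance and 1 standard error. Groups of microRNAs were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, adjusted over the 14 groups with at least 3 tested members. Groups were a let-7 family, miR-17 clusters, epithelial, striated muscle, neural, liver and gut, blood cells, smooth muscle and endothelium, mesenchyme, pancreas and endocrine, pluripotent and placental, Dlk1-Dio3 imprinted, Hox-cluster, reported to target ER-alpha mRNA, and p68-linked processing. An assay belongs to a group by its name without species prefix, arm and copy suffix, and both arms count as separate assays. File tables were read with Python 3.11.15 and pandas 2.3.3, Fisher's exact test was run with scipy 1.17.1 and plots were drawn with matplotlib 3.10.9.

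The named microRNAs follow a rule set before the data were examined: those past the threshold, filled up to 20 by the smallest unadjusted p; up to 3 members of each group with the largest absolute fold change; the controls; up to 5 detected in 1 group only; and the 5 most abundant. Alternatives were the scaling to the controls, no normalization, quantile normalization, detection at a Ct of 32, no filter with undetermined wells at cycle 40, each sample left out, the replicate number as a block, ordinary variances, and eBayes with trend and robust settings. After seeing the data, removal of the constant from wild-type replicate 1 and centring on the average profile were added. The procedure was tested on simulated data for the comparison of ER-alpha knockout with wild-type (229 assays, 100 runs). The noise was normal and independent, with 1 SD per sample estimated from the data and shared by all assays. It called 12.2%, 62.8% and 95.9% of assays changed by 1, 2 and 3 log2 units, and 1.95% of its calls were on unchanged assays. In 100 runs without change, 2 had any call. The simulation left out spread that differs by assay, the near whole-cycle values of wild-type replicate 1 and deviations shared between samples. These rates may therefore not hold for the data.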

Results

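MicroRNA levels were surveyed by TaqMan real-time PCR in whole C57BL/6 mouse embryos at E18.5, in 2 wild-type samples and 2 samples with a knockout of estrogen receptor alpha (ER-alpha, the nuclear estrogen receptor encoded by Esr1). The assays read small RNAs, so the transcript of the targeted gene was not analysed here. Each well gives a threshold cycle (Ct), where a lower Ct means more RNA and 1 cycle is close to 1 log2 unit. In all 4 samples 380 assays were read, of which 375 target microRNAs and 5 are small-RNA controls. Names are those of the assay panel, with the prefix mmu for mouse and rno for rat sequences. PCR gives no read counts, so the depth of a sample is described here by how many microRNAs amplified. At a Ct of 35 or lower, 290 and 254 microRNAs were detected in wild-type replicates 1 and 2, and 260 and 259 in ER-alpha knockout replicates 1 and 2. In all 4 samples 229 microRNAs were detected, and these were tested; 63 were detected in no sample. The sample titles number whole embryos, but the labels do not say whether a sample was 1 embryo or a pool, or whether litters differed, so p-values measure only the spread between these samples, part of which may be technical.

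The microRNAs with the earliest mean Ct were mmu-miR-133a, a striated-muscle microRNA, mmu-miR-126-3p, an endothelial microRNA, mmu-miR-16, mmu-miR-24 and mmu-miR-19b. This order sets different assays of unknown efficiency side by side, and without wild-type replicate 1 mmu-miR-17 (mean Ct 21.4; named after its value was seen) came before mmu-miR-19b (21.5). Relative to the median microRNA of a sample, mmu-miR-133a stood at 7.53 ± 0.62 log2 units in wild-type and 8.02 ± 0.29 in ER-alpha knockout embryos (SD, n = 2 each). The level of mmu-miR-126-3p was 7.60 ± 0.57 in wild-type and 7.84 ± 0.25 in knockout samples (SD, n = 2 each), and log2 fold changes of mmu-miR-16, mmu-miR-24 and mmu-miR-19b were 0.74, 0.21 and -0.22 (0.52, 0.41 and -0.13 without wild-type replicate 1).

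Wild-type replicate 1 stood apart from the other 3 samples. Over the 229 shared assays, which are not independent replicates, its Ct values had Pearson correlations of 0.939 to 0.954 with the other samples, and the other samples had 0.978 to 0.989 with each other. Of its 341 amplified wells, 90.0% lay within 0.1 cycle of a whole cycle once a constant of 0.273 shared by its 380 wells other than U6 was taken off; in the other samples 21.0% to 26.5% did, and 20% is the share of chance. It also accounted for 40 assays detected in it alone, while wild-type replicate 2 had 2, ER-alpha knockout replicate 1 had 3 and replicate 2 had 0.

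**Figure D1:**
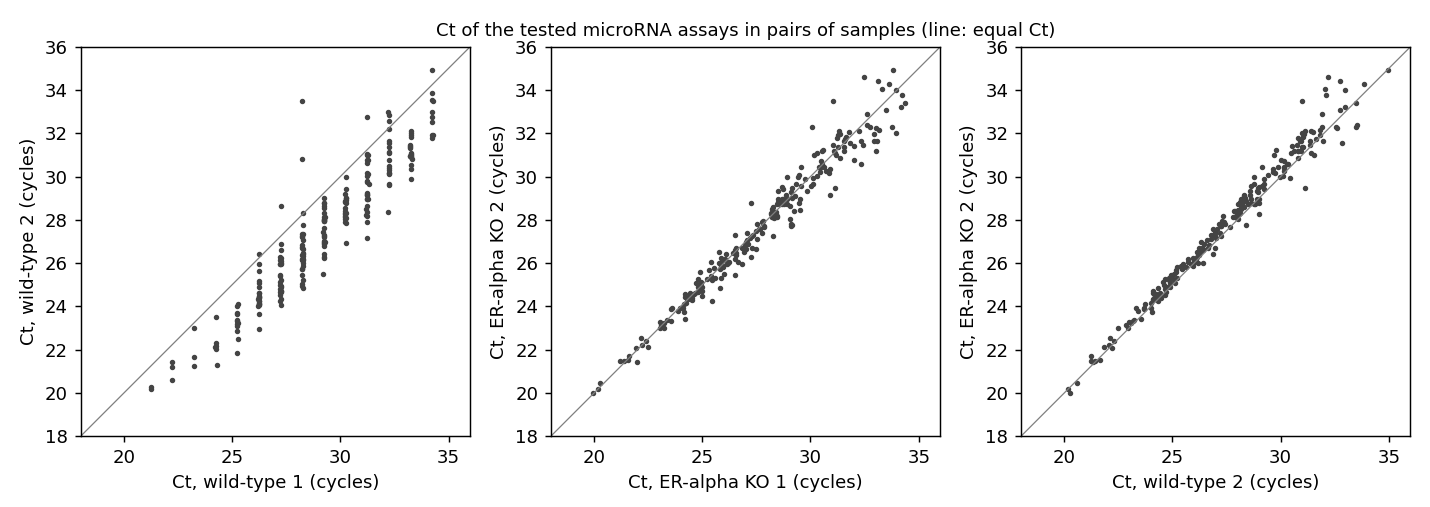
Ct (cycles) of the 229 tested microRNA assays, each point 1 assay, in 3 pairs of samples: wild-type replicates, ER-alpha knockout replicates, and replicate 2 of both genotypes; the line marks equal Ct. The points of wild-type replicate 1 lie in columns at whole-cycle steps and at later Ct (median difference 1.84 cycles from wild-type replicate 2), while the other pairs follow the line with correlations of 0.981 and 0.989.

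**Figure D2:**
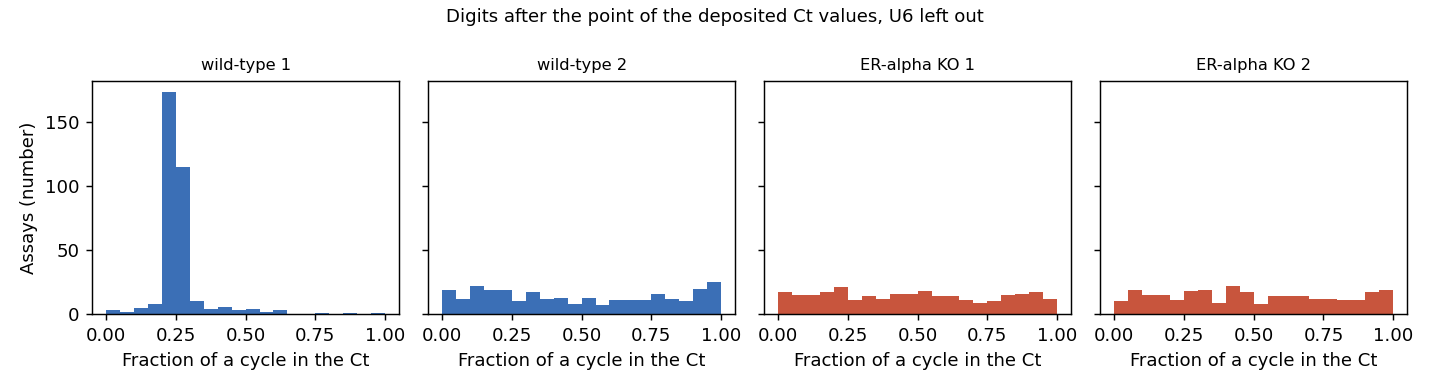
Histogram of the part of the Ct after the decimal point (x, fraction of a cycle) for the amplified assays other than U6 (y, number of assays), 1 panel per sample. In wild-type replicate 1, most assays share 1 fraction near 0.273, and the other 3 samples are spread over the cycle.

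The first comparison asked which microRNAs differ between ER-alpha knockout and wild-type embryos. MicroRNAs at lower relative levels in knockout embryos included mmu-miR-324-3p at 0.22-fold of wild-type (log2 fold change -2.18), mmu-miR-181c at 0.31-fold (-1.69) and mmu-miR-34c, of a p53-responsive family, at 0.33-fold (-1.59). At higher levels, mmu-miR-98, a let-7 relative, was at 3.01-fold (1.59), mmu-miR-188-5p at 2.92-fold (1.55) and the brain-enriched mmu-miR-138 at 2.63-fold (1.39). Levels of mmu-miR-34c were -4.39 ± 0.47 in wild-type and -5.98 ± 0.07 in knockout samples, and those of mmu-miR-98 were -3.89 ± 0.21 and -2.30 ± 0.89 (log2 units, SD, n = 2 each). None of these differences passed the test, and they are given as values. Mean Ct values over all samples were 32.1 for mmu-miR-324-3p, 33.3 for mmu-miR-181c and 33.3 for mmu-miR-34c. They were 31.2 for mmu-miR-98, 29.4 for mmu-miR-188-5p and 24.8 for mmu-miR-138. Levels are less certain for the assays closer to the detection limit. For 16 of the 20 assays with the smallest unadjusted p, both knockout samples lay on the same side of both wild-type samples, the exceptions being mmu-miR-103, mmu-miR-199a-5p, mmu-miR-674 and rno-miR-532-5p. Chance separates 33.3% of assays in this way, and more of those picked for a small p.

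Of the 229 microRNAs tested with limma, 0 passed an adjusted p of 0.05, and the smallest adjusted p was 0.160, for mmu-miR-324-3p (levels -2.81 ± 1.14 in wild-type and -4.99 ± 1.10 in knockout). Without adjustment, 10 had a p under 0.05, 3 with a higher and 7 with a lower level in ER-alpha knockout. That split depended on the fit: with ordinary variances 8 of 9 were higher and with trend and robust settings 10 of 12, and 0 passed the adjusted threshold in either. It also depended on the centring and filter: 5 of 10 were higher with quantile normalization and 2 of 3 with control scaling. Average-profile centring gave 1 of 4 and a Ct of 32 gave 0 of 3. The median of all fold changes was 0.26 here and -0.05 with average-profile centring. Leaving out a sample puts 1 sample in its group, so the spread then comes from the other group alone, and counts from such fits are not given. Beyond those named above, the 10 of the main fit held rno-miR-532-5p (-1.63), mmu-miR-674 (-1.62), mmu-miR-199a-5p (-1.58) and rno-miR-450a (-1.32). Each fold change had a standard error of 0.64 log2 units, and at least 2.38-fold was needed to reach an unadjusted p of 0.05. The remaining assays among the 20 with the smallest p were mmu-miR-539 (1.21), mmu-miR-350 (1.12), rno-miR-196c (1.11), mmu-miR-7b (1.11), mmu-miR-493 (1.00) and mmu-miR-196b (0.99) at higher levels in knockout embryos. At lower levels were mmu-miR-181a (-1.16), mmu-miR-339-5p (-1.07), mmu-miR-344 (-1.05) and mmu-miR-103 (-1.03). The size of several of these rested on wild-type replicate 1: without it, the log2 fold changes were -0.70 for mmu-miR-181c, 0.18 for mmu-miR-539, 0.50 for mmu-miR-350, -0.40 for mmu-miR-103, -1.06 for mmu-miR-674, 0.23 for mmu-miR-188-5p, 0.39 for mmu-miR-138, -0.23 for mmu-miR-199a-5p and 0.27 for rno-miR-532-5p, which changed direction. Those of mmu-miR-324-3p (-1.70), mmu-miR-34c (-1.58), rno-miR-450a (-1.33), mmu-miR-7b (1.37), rno-miR-196c (1.07) and mmu-miR-196b (0.91) moved less. Of these assays, mmu-miR-34c, rno-miR-450a and mmu-miR-7b had late mean Ct values of 33.3, 33.2 and 33.2, so their levels are less certain. The mean Ct was 32.1 for mmu-miR-324-3p, 28.9 for rno-miR-196c and 26.9 for mmu-miR-196b.

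**Figure D3:**
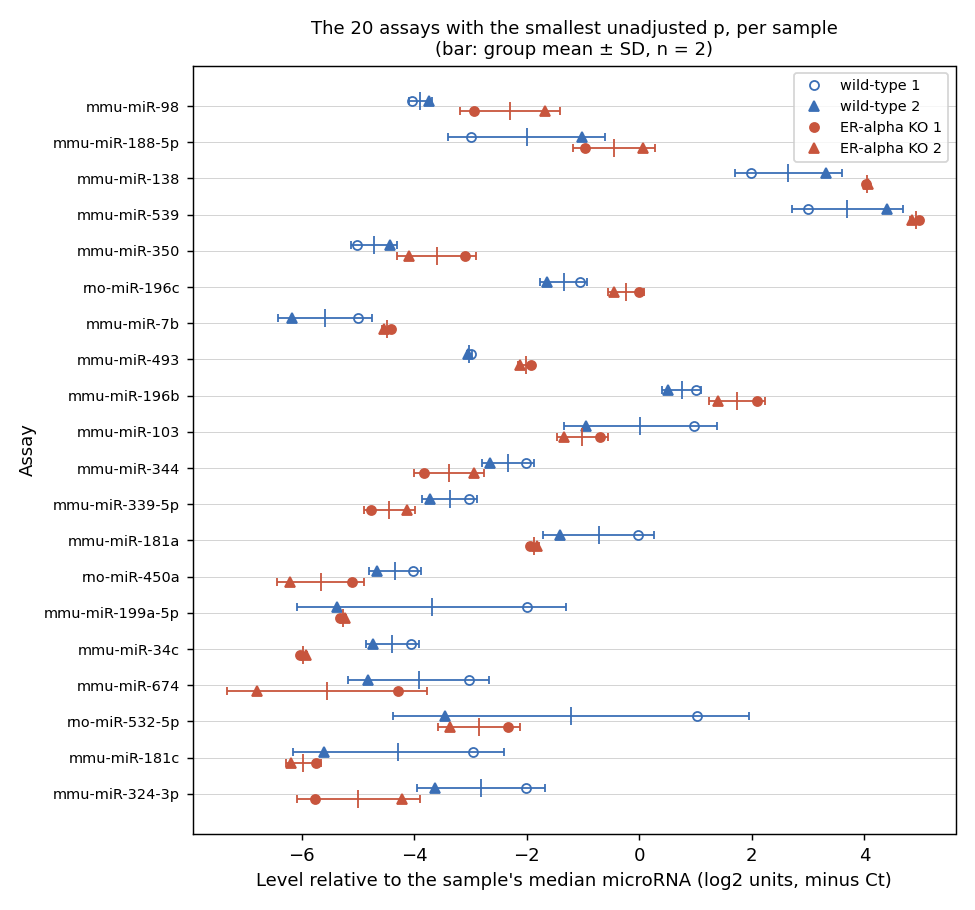
Level relative to the median microRNA of the sample (x, log2 units, minus Ct) of the 20 assays with the smallest unadjusted p (y), with 1 symbol per sample (blue wild-type, red ER-alpha knockout, circle replicate 1, triangle replicate 2; bars, group mean ± SD, n = 2). Both mmu-miR-34c knockout samples lie near -5.98, below both wild-type samples; for rno-miR-532-5p the wild-type samples lie 4.47 log2 units apart.

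Groups of microRNAs typical of a tissue, cluster or family were set before the data were examined, and 14 of the 15 groups had at least 3 tested members. The median log2 fold change of all 229 microRNAs was 0.26, not 0, so members are counted as above or below that value. Members of the let-7 family, which accumulates with differentiation, had a median of 0.15 with 3 of 9 above 0.26 (mmu-miR-98 1.59, mmu-let-7g 0.73, mmu-let-7e 0.59). The miR-17 clusters, linked to proliferation, had a median of 0.50 with 7 of 11 above 0.26, among them mmu-miR-25 (0.71) and mmu-miR-92a (0.67). Blood-cell microRNAs, which residual blood would also bring, had the largest group median at 0.63, with 6 of 7 above 0.26 (mmu-miR-155 0.91, mmu-miR-150 0.69). MicroRNAs reported in human cells to target ER-alpha mRNA had a median of 0.60 with 3 of 5 above 0.26, mmu-miR-193b at 0.96 and mmu-miR-222 at 0.77; without wild-type replicate 1 the median was -0.0043, mmu-miR-193b 0.30 and mmu-miR-222 -0.0043. Those of pancreas and pituitary had 0.57 with 3 of 4 above 0.26 (mmu-miR-7b 1.11, mmu-miR-216b 0.57), and those of liver and gut had 0.47 with 3 of 4 above 0.26 (mmu-miR-122 0.78, mmu-miR-192 0.51). Most of these members rested on wild-type replicate 1 too. Without it, mmu-let-7e (-0.33), mmu-miR-25 (-0.19), mmu-miR-92a (-0.58) and mmu-miR-150 (-0.11) changed sign, and mmu-let-7g (0.08), mmu-miR-155 (0.17), mmu-miR-216b (0.33), mmu-miR-122 (0.28) and mmu-miR-192 (0.07) came closer to 0. The median of all assays was -0.03 without that sample, so part of these moves is shared by all assays.

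Striated-muscle microRNAs had a median of 0.42 with 3 of 5 above 0.26 (rno-miR-1 0.57, mmu-miR-133a 0.49), and epithelial microRNAs one of 0.38 with 5 of 9 above it (mmu-miR-203 0.81, mmu-miR-205 -0.46). Mesenchymal microRNAs had a median of 0.30 with 5 of 8 above 0.26, with mmu-miR-199a-3p at 0.58 and its partner arm mmu-miR-199a-5p at -1.58. Smooth-muscle and endothelial microRNAs had a median of 0.20 with 1 of 4 above 0.26 (mmu-miR-126-5p 0.62, mmu-miR-126-3p 0.24, mmu-miR-143 0.16). Among 37 microRNAs of the imprinted Dlk1-Dio3 domain the median was 0.19 and 18 lay above 0.26, with mmu-miR-539 at 1.21 and mmu-miR-431 at 0.92. Neural microRNAs had a median of 0.14 with 6 of 13 above 0.26, with mmu-miR-138 at 1.39 and mmu-miR-124 at -0.92. Hox-cluster microRNAs had a median of 0.07, with 1 of 3 above 0.26 (mmu-miR-196b 0.99). MicroRNAs reported to be processed with the helicase p68 had a median of 0.09 and a mean of -0.07, with 2 of 6 above 0.26 (mmu-miR-16 0.74, mmu-miR-199a-5p -1.58). The camera test, which sets a group against all other assays, put the p68, neural and mesenchymal groups below the rest although their medians were above 0 and the mesenchymal median above 0.26. Without wild-type replicate 1, mmu-miR-203 changed sign (-0.08), and values closer to 0 were seen for mmu-miR-205 (-0.10), rno-miR-1 (0.11), mmu-miR-199a-3p (0.16), mmu-miR-126-5p (0.12) and mmu-miR-431 (0.49). The value of mmu-miR-199a-5p, which enters both the p68 and the mesenchymal group, was -0.23 without that sample.

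By limma's camera test, 0 of the 14 groups passed; the smallest adjusted p was 0.788, and 0 members passed, both over all assays and adjusted over the list alone. With an estimated correlation the smallest adjusted p was 0.932, and the fry test, which asks whether members move 1 way, gave a smallest adjusted p of 0.245. Centring on the average profile of the samples changed the sign of 7 of the 14 medians, and leaving out wild-type replicate 1 that of 8, namely of the blood-cell (-0.19), let-7 (-0.25), miR-17 (-0.12), neural (-0.15), Hox-cluster (-0.14), pancreas (-0.014), epithelial (-0.011) and ER-alpha-targeting (-0.0043) groups. Without that sample, the medians that kept their sign were 0.13 for liver and gut, 0.17 for striated muscle and 0.11 for mesenchyme. Those of smooth muscle and endothelium (0.17), Dlk1-Dio3 (0.10) and p68 (0.0012) kept it too. The median of all assays fell from 0.26 to -0.03, and the sign changes partly follow that fall. Set against it, the blood-cell and miR-17 groups went from above to below. The smooth-muscle, Dlk1-Dio3 and p68 groups went from below to above, and the others kept their side. The pluripotent and placental group had 0 of 12 assays detected in all 4 samples; mmu-miR-292-3p amplified at a Ct of 32.2 in wild-type replicate 2 and 34.7 and 33.1 in the knockout samples, and at 36.2 in wild-type replicate 1.

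**Figure D4:**
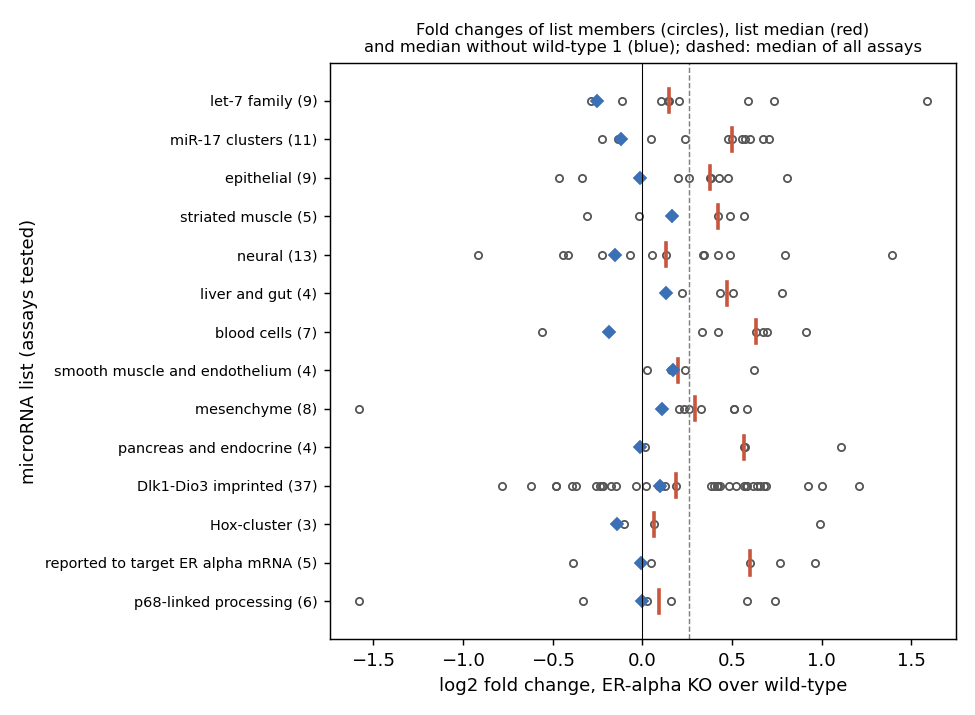
Log2 fold change, ER-alpha knockout over wild-type (x), of the tested members of each group (y; circles, 1 per assay; number of assays in brackets), with the median (red) and the median without wild-type replicate 1 (blue diamond); the dashed line is the median of all assays, 0.26. All 14 medians lie above 0 with all samples, and 8 of the 14 have the opposite sign without wild-type replicate 1. Without that sample the median of all assays is -0.03.

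The second comparison asked whether microRNAs as a whole differ in amount, with values scaled to the 5 small-RNA controls. The median microRNA stood at -3.91 ± 1.01 log2 units relative to the controls in wild-type and -3.64 ± 0.36 in ER-alpha knockout embryos (SD, n = 2 each), a difference of means of 0.28. The exact permutation test gave a two-sided p = 1, where 0.333 is the smallest p that 2 against 2 samples can give. The median over assays of the log2 fold change was 0.54, and it was -0.14 without wild-type replicate 1 and 1.21 without wild-type replicate 2. Among the controls, the Ct difference of ER-alpha knockout minus wild-type was -0.23 for MammU6, 0.14 for U87, 0.58 for Y1, -0.27 for snoRNA135 and -0.28 for snoRNA202. Scaled to Y1 alone, the median was 1.14, and to snoRNA202 or snoRNA135 alone 0.28.

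The third comparison asked which microRNAs were detected in both samples of 1 genotype and in neither sample of the other. In ER-alpha knockout embryos 2 met this, mmu-miR-547 (Ct 34.9 and 33.0 in knockout, 36.2 and 36.4 in wild-type) and mmu-miR-671-3p (34.8 and 33.8 against 35.3 and 35.7). In wild-type embryos 0 did. These Ct values lie close to the detection limit of 35, and no test was made per assay. With the limit at 38 the counts were 0 for knockout and 5 for wild-type, and without wild-type replicate 2 they were 14 and 40.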

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

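The tests of wild-type replicate 1 against more template and against a processing fault were chosen after its values were seen, and the tests of rounding and of a compressed scale before their results.

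A plant control assay, ath-miR159a, amplified at a Ct of 29.3 in wild-type replicate 1, a signal in data outside the comparisons. It was read in that sample only, which held 381 assays against 380 in each other sample. Whether it would amplify in the other samples cannot be told. In the same sample 40 microRNAs were detected that were detected in none of the other 3, among them mmu-miR-679 (Ct 23.6), mmu-miR-147 (24.4) and rno-miR-343 (27.1), which were chosen after their values were seen; 27 of the 40 did not amplify in the other 3. More template in that sample is argued against, because its shared assays came up later, not earlier, by a median of at least 1.44 cycles. Of the 40, 55% lay off the whole-cycle grid against 0 of the 229 shared assays (Fisher's exact test p = 1.08e-21), so their readings differ from those of the shared assays. In the other samples only 21.0% to 26.5% of wells lay within 0.1 cycle of a whole cycle. The plant control lay 0.055 cycles from a whole cycle once the constant was taken off. The test therefore cannot say which wells of this sample, if any, hold a fault in reading or processing. No biological explanation for a single embryo sample was tested.

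The larger scatter of wild-type replicate 1 (robust SD of Ct differences 0.83 to 0.89 cycles, against 0.31 to 0.44 among the other samples) has 2 simple technical candidates. Rounding another sample to whole cycles raised the robust SD to at most 0.627, short of the scatter seen, so whole-cycle readings are not the whole cause. Rescaling its Ct by the slope on the other samples (0.884) left the robust SD at 0.893 or more. The rescaled values still held the whole-cycle readings, which add scatter of their own, so this test cannot decide on a compressed scale. Rounding and compression together were not tested. A different plate lot, RNA quality or the embryo itself may remain. The 4 U6 wells of wild-type replicate 1 spanned Ct 15.58 to 16.72. They spanned 15.79 to 15.97 in wild-type replicate 2, 15.76 to 15.90 in ER-alpha knockout replicate 1 and 15.39 to 15.79 in replicate 2. Wells of 1 sample share their RNA, so this wider span argues against RNA quality or the embryo as its source, for U6 only. The microRNA assays have 1 well each, and for them these data hold no value that separates the candidates.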

How the results depend on the processing

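The removal of the constant from wild-type replicate 1 and the centring on the average profile were chosen after seeing the data. Among alternatives that kept all samples, the count of microRNAs past the threshold was 0 but for the replicate number as a replicate block. That fit called 1 (mmu-miR-324-3p, limma adjusted p = 0.00578). In the others the smallest limma adjusted p ranged from 0.222 (constant removed from wild-type replicate 1) to 0.9996 (no normalization). For mmu-miR-324-3p itself the replicates differed in opposite directions. Its levels in replicates 1 and 2 were -2.01 and -3.62 in wild-type, and -5.77 and -4.21 in ER-alpha knockout. The block therefore took up little of the spread of that assay, and its call rests on the variance that limma shares over assays. Same-numbered samples deviate together (r = 0.37 over assays), but with 2 pairs, and no label that says what a number marks, they were not treated as pairs, and no group of microRNAs was called under the block. Unadjusted p under 0.05 was met by 4 microRNAs with average-profile centring, 3 with control scaling or a Ct of 32, 19 under the replicate block, and 0 with no normalization. Fits with a sample left out have 1 sample in a group, so their p-values rest on the spread of the other group alone. Groups of microRNAs past the threshold numbered 0 in each alternative run for them; ordinary variances and the trend and robust settings were not run for groups. The median log2 fold change of all assays moved from 0.26 to 0.05 with quantile normalization, 0.54 with control scaling and -0.05 with average-profile centring; both knockout samples lay above both wild-type samples for 76 and below for 14 assays (38.2 each by chance), and for 34 and 34, 47 and 15, and 47 and 42 in those. Over named microRNAs and alternatives 38 values changed sign, 12 of them without wild-type replicate 1; sign changes of values that no fit called are counted, not called reversals. Of the 20 leading microRNAs, 19 kept their sign in the alternatives run for them, rno-miR-532-5p being the exception. In all, 13 alternatives covered all 20, and the Ct of 32 only 7. Ordinary variances, the trend and robust settings, the replicate block and no filter leave the fold changes of these assays unchanged. Those alternatives could not change a sign. The 20 were also picked for a small p in these same samples. The shift of all microRNAs ranged from -0.14 to 1.21 over the samples left out, from 0.28 to 1.14 over single controls, and was 0.63 at a Ct of 32. Counts detected in 1 genotype only were, for ER-alpha knockout, 1 at a Ct of 32, 0 at 38, 1 at any Ct and 2 to 14 over the samples left out; for wild-type they were 1, 5, 7 and 2 to 40. A pseudocount was not run, since Ct values need none. Assays near a Ct of 35 have the least certain levels.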

Other observations

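The families and assays of this paragraph were chosen after their values were seen; of them mmu-miR-196b also belongs to the Hox-cluster group. Both miR-181 assays were lower in ER-alpha knockout embryos (mmu-miR-181a -1.16, mmu-miR-181c -1.69; -0.79 and -0.70 without wild-type replicate 1), as log2 fold changes. Both miR-196 assays were higher (mmu-miR-196b 0.99, rno-miR-196c 1.11; 0.91 and 1.07 without that sample). These 4 kept their sign in the alternatives run for them, not all of which can change a sign, while 0 passed the threshold. At a Ct of 32, mmu-miR-181c was not among the assays. By contrast, all 5 miR-30 assays were above 0 with a median of 0.57, which became -0.03 without wild-type replicate 1. The assays rno-miR-532-5p and mmu-miR-532-5p were at -1.63 and 0.77, and at 0.27 and 0.19 without wild-type replicate 1. The 2 arms mmu-miR-324-5p and mmu-miR-324-3p were at -0.70 and -2.18. Without wild-type replicate 1, log2 fold changes were 1.46 for mmu-miR-685, -1.58 for mmu-miR-34c, 1.37 for mmu-miR-7b and 1.07 for rno-miR-196c. That fit has 1 wild-type sample, so its spread comes from the knockout samples alone, and these are given as values only.

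The tests of the replicate numbers were chosen after their result was seen, and that of the hairpins before. Split by replicate number instead of genotype, 5 microRNAs passed the adjusted threshold (mmu-miR-687, rno-miR-532-5p, mmu-miR-376b, mmu-miR-674 and mmu-miR-384-3p), against 0 for genotype and 0 for the crossed split. The level of mmu-miR-687 was higher in replicate 1 than in replicate 2 by 7.13 log2 units in wild-type and 2.62 in ER-alpha knockout, and the Ct of U87 differed by -1.54 and -2.18 cycles (replicate 1 minus 2). The differences within wild-type and within knockout correlate over assays (r = 0.369, permutation p = 1e-04, the smallest 10000 permutations can give). The permutation shuffles assays, which are not independent, and each genotype gives only 1 such difference. It therefore cannot decide whether wild-type replicate 1 alone is the source. Over the 224 assays other than those 5, r was 0.22 (permutation p = 0.0012). A litter, sex, plate or RNA batch shared by same-numbered samples may be the source, and these cannot be told apart here because the labels give none of them.

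A hypothesis was that the fold changes follow the amount of the hairpin, so that 2 assays from 1 hairpin should change together. Over the 19 hairpin names with exactly 2 tested assays, some paired as a mouse and a rat assay of 1 name, the correlation of log2 fold changes was 0.258. The one-sided permutation p was 0.12 (Spearman 0.20, permutation p = 0.10), and the bootstrap interval was -0.22 to 0.57. Names with more tested assays, such as miR-532, were left out. The mouse and rat assays of miR-1, miR-224, miR-351 and miR-381 have no arm in their names and may read the same arm. Such pairs could agree whatever the amount of the hairpin, so they do not test the hypothesis. Of the 19, 14 had the same sign, but the median of all fold changes was 0.26, which raises the share of equal signs by chance. Without the 2 hairpins farthest from the median the correlation was -0.04. Such hairpins add most to a correlation of this kind, so that drop says little about the hypothesis. Without wild-type replicate 1 the correlation was 0.297. The bound set beforehand took a p of 0.05 or more as evidence against the hypothesis, which was wrong because a p that misses the threshold excludes nothing, and the interval holds values on both sides of 0; the question may stay open until more hairpins are measured.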
